A study of Mus musculus with 8 samples.

How the data were processed

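Bulk RNA sequencing was done on liver RNA from mice on a diet high in fat and fructose for 16 weeks, with 4 libraries labelled miR-93 knockout and 4 labelled wild type. The deposited file holds raw gene counts that the authors made from the reads, with no normalization, for 56748 Ensembl gene IDs. The submitters' processing notes name cutadapt 4.2 for trimming, STAR 2.7.10a for alignment and the mm39 genome build. How reads that match several genes were counted is not given in the sources used here. Reads were not used here.

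Counts were read into R 4.3.3. Gene symbols came from GENCODE M21, which is built on GRCm38 and not on mm39, so it served for names, the order of neighbouring genes and 3′ UTR sequence, and no coordinates are given. It named 52073 of the IDs, and 4675 had no symbol and took 0.332% to 1.57% of the counts of a library. Total counts ran from 5085860 to 10966019 per library. A count of 0 allows up to 3 counts, which by raw library size is 0.274 CPM in the deepest library and 0.590 CPM in the shallowest. The levels reported below are scaled further, which raises this limit in the shallowest library, wild-type replicate 4. There 4 counts of Cyp4a14 read 2.25 CPM after scaling.

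The test of knockout against wild type, the only contrast the labels give, was edgeR 4.0.16 with quasi-likelihood fits (robust), TMM factors and genes kept by filterByExpr on the genotype groups, which left 13204 of 25937 detected genes. It was two-sided with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. No covariate or block was used, since the labels name no batch or sex and the replicate numbers were not found to pair the libraries.

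Gene lists and cell type marker lists, 27 and 14 in number, were written before the data were examined, as were the tests, the naming rule and most of the alternatives. The 37 with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and the preset correlation of 0.01, adjusted over these lists. Named genes were, always, Mir93, Mir25, Mir106b, Mcm7 and Sirt1, then the 12 higher and the 12 lower genes with the largest log2 fold change. These came from the 1300 higher and 1265 lower genes past the threshold with a mean of at least 1 CPM and groups that do not overlap. Predicted genes and pseudogenes were skipped, 3 among the higher and 11 among the lower genes before the 12 were reached. For each list described, up to 4 members with the smallest p were added, and some that this rule takes are not reported here. A gene named outside this rule is said to have been named after its values were seen.

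Matches to positions 2 to 8 of miR-93-5p were counted with Biostrings 2.70.1 in the longest annotated 3′ UTR of each gene. The difference in mean log2 fold change between genes with and without a match, with UTR length as a covariate, was ranked among the 419 other 7-mers of the same bases. Principal components used the 500 most variable tested genes. Single measures per library were compared with exact permutation tests. Figures were drawn with matplotlib 3.10.9.

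The steps were tested on simulated data for this comparison with 12994 genes. Of 100 genes planted at a log2 change of 1, 65 were recovered, and of 100 planted at 2, 95 were, with 1.23% false among 162 calls. All simulated libraries shared the same spread for a given gene, while in the real data wild-type replicate 4 stood apart. The recovered and false shares may therefore differ in the real libraries. The planted list was called (camera p with the preset correlation 3.03e-22) and 0 of 20 random lists were. The simulated genes were drawn independently, so this does not check the preset correlation against that of real genes. A seed effect of 0.1, added directly to the simulated fold changes, was estimated as 0.0963, against -0.0037 without it. That checks only the arithmetic of the fit.

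Alternatives were other scalings (DESeq2 1.42.0 size factors, upper quartile, library size only), other filters, DESeq2 and limma-voom with and without quality weights, a replicate block, a minimum fold of 1.5, fry and an estimated correlation for the lists, other UTR choices for the seed, and each library left out in turn. Leaving out the mitochondrially encoded genes, thinning all libraries to the same nuclear depth and using the log2 UTR length were added after seeing the data. No library was left out of the reported comparison. Marker lists with fewer than 5 tested members were not tested as sets.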

Results

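The series profiled RNA from the livers of mice on a diet high in fat and fructose, labelled as metabolic dysfunction-associated steatotic liver disease (MASLD) at 16 weeks. Of the 8 libraries, 4 carry the miR-93 knockout label and 4 the wild-type label, all on the same diet. The single comparison asked which liver transcripts differ when the microRNA miR-93 is missing, and the series title names the deacetylase Sirt1 as the proposed target. The knockout libraries held 9187279 to 10966019 counts over genes and the wild-type libraries 5085860 to 7451026. Transcripts of the mitochondrial genome took 8.08%, 9.30%, 11.7% and 15.03% of the counts in the 4 knockout libraries and 41.7% ± 24.4 (SD, n = 4) in the wild-type libraries, where they ran from 25.4% to 77.8%. Every wild-type library lay above every knockout library in that share and below every knockout library in total counts, each with a two-sided exact permutation p of 0.0286, the smallest that the 70 assignments of 4 and 4 libraries allow. Wild-type replicate 4 stood apart: 77.8% of its counts were mitochondrial (95% exact binomial interval 77.7% to 77.8%). It had 14287 genes with a count against 18412 to 20148 in the other libraries, and 1131446 of its counts lay outside the mitochondrial genome. Such intervals, and the limits given for counts of 0, cover counting error only. The principal component with the most variance (73.4%) set this library against the others, and the next one (20.7%) separated the remaining libraries by genotype. Fold changes below are knockout over wild type on the log2 scale, ± the standard error of the edgeR fit over all 8 libraries, with Benjamini-Hochberg adjusted p. The labels do not say whether the 4 libraries of a genotype came from separate animals, so the p-values measure the spread between these libraries only and a difference can also be technical.

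**Figure D1:**
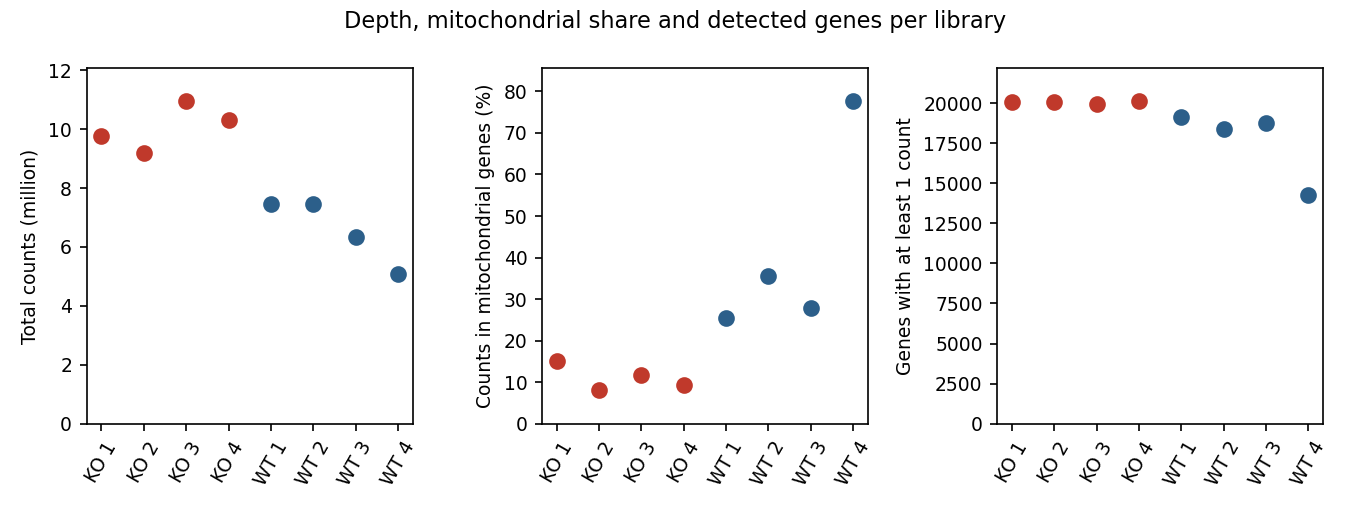
Total counts, percent of counts in mitochondrially encoded genes and number of genes with at least 1 count, one point per library (KO, miR-93 knockout, red; WT, wild type, blue). Wild-type replicate 4 lies at 77.8% mitochondrial counts and 14287 genes, away from the other 3 wild-type libraries at 25.4% to 35.5% and 18412 to 19131 genes.

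The deleted gene and the proposed target were examined first. Mir93 (ENSMUSG00000065527) and its cluster neighbours Mir25 and Mir106b had 0 counts in every library of both genotypes, so the counts do not check the knockout label. By raw library size 3 counts would be 0.274 CPM in the deepest library and 0.590 CPM in the shallowest. Mcm7, the replication helicase gene whose intron holds the cluster, had a log2 fold change of -0.27 ± 0.14 (adjusted p = 0.188). Sirt1 (ENSMUSG00000020063) had 13.5 ± 1.72 CPM in knockout and 18.0 ± 6.09 CPM in wild type (SD, n = 4 per group). Its log2 fold change of -0.34 ± 0.21 did not pass the threshold (adjusted p = 0.268), with a 95% interval of -0.79 to 0.11. Wild-type replicate 4 held the highest Sirt1 level, 27.0 CPM, and without it the change was -0.14 (adjusted p = 0.484). With scaling by library size alone, which raises the median gene by 0.55, Sirt1 and Mcm7 both read 0.30, below that median, and neither was called. In a list of 20 SIRT1 and AMPK signalling genes, Foxo1 rose (0.45 ± 0.12, adjusted p = 0.0224) and Nmnat1 (-0.61 ± 0.14, adjusted p = 0.0105) and Ppargc1b (-1.60 ± 0.48, adjusted p = 0.0371) fell, and 17 did not pass. In this list 1 gene rose and 4 fell without wild-type replicate 4. The same 3 were past the threshold adjusted over the list alone. The list as a whole was not called by camera (adjusted p = 0.0798), while the alternative test, fry, called it (adjusted p = 0.0153). Foxo1 and Ppargc1b lost their calls without knockout replicate 2, 3 or 4 or wild-type replicate 2 or 3, with adjusted p of 0.0521 to 0.0751 for Foxo1 and 0.0506 to 0.101 for Ppargc1b. Nmnat1 was not called with the replicate block (0.0697), without a filter on low counts (0.0523), after thinning to equal nuclear depth (0.0808) or with library size only (-0.04, 0.944).

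Many liver transcripts differed between the genotypes. The 12 named genes with the largest rises were led by Cyp4a14, a fatty acid omega-hydroxylase (6.84 ± 0.46, adjusted p = 3.26e-06), the metallothionein Mt2 (6.28 ± 0.24, adjusted p = 4.94e-08), the siderophore-binding protein Lcn2 (6.24 ± 0.25, adjusted p = 5.04e-08) and the serum amyloid genes Saa1 (6.10 ± 0.19, adjusted p = 1.33e-08) and Saa2 (5.69 ± 0.21). Mt1 (4.76), Cyp4a10 (4.62), Nlrp12 (4.55), Cyp4a31 (4.55), the neutrophil protease gene Prtn3 (4.51), the fasting hormone gene Fgf21 (4.42) and the hepatokine gene Fgl1 (4.06) followed. The wild-type libraries held 0 to 2 counts each of Prtn3, 0 to 5 of Fgf21 and 0 to 9 of Cyp4a31, so the size of these 3 rises is uncertain. Saa1 stood at 1575 ± 84.4 CPM in knockout and 22.7 ± 4.40 CPM in wild type (SD, n = 4 per group). The 12 named genes with the largest falls were led by Chrna4, a nicotinic receptor subunit (-7.78 ± 0.50, adjusted p = 2.34e-06), which had 0.154 ± 0.179 CPM in knockout, from 0 or 4 counts per library, and 38.8 ± 15.5 CPM in wild type (SD, n = 4 per group). The glutathione transferase Gsta1 (-6.28 ± 0.60), Cib3 (-5.93 ± 0.25), the hepcidin paralog Hamp2 (-5.86 ± 0.39), the desaturase Scd1 (-5.54 ± 0.22), the lipogenic regulator Thrsp (-5.30 ± 0.16) and the elongase Elovl6 (-4.89 ± 0.37) came next, then the mitochondrial serine tRNA gene mt-Ts1 (-4.06, or -3.38 with an adjusted p of 0.0493 without wild-type replicate 4 and not called without a filter on low counts), the fatty acid synthase Fasn (-4.00), Gstm3 (-3.86), Gbp11 (-3.83) and Cabyr (-3.81). In all of these 24 genes every knockout library lay on one side of every wild-type library, which the naming rule required. Saa1 and Saa2, Mt1 and Mt2, the Cyp4a genes, the glutathione transferases and Hamp2 have near-identical relatives, and how the authors' counting divided reads among copies is not given in the sources used here.

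**Figure D2:**
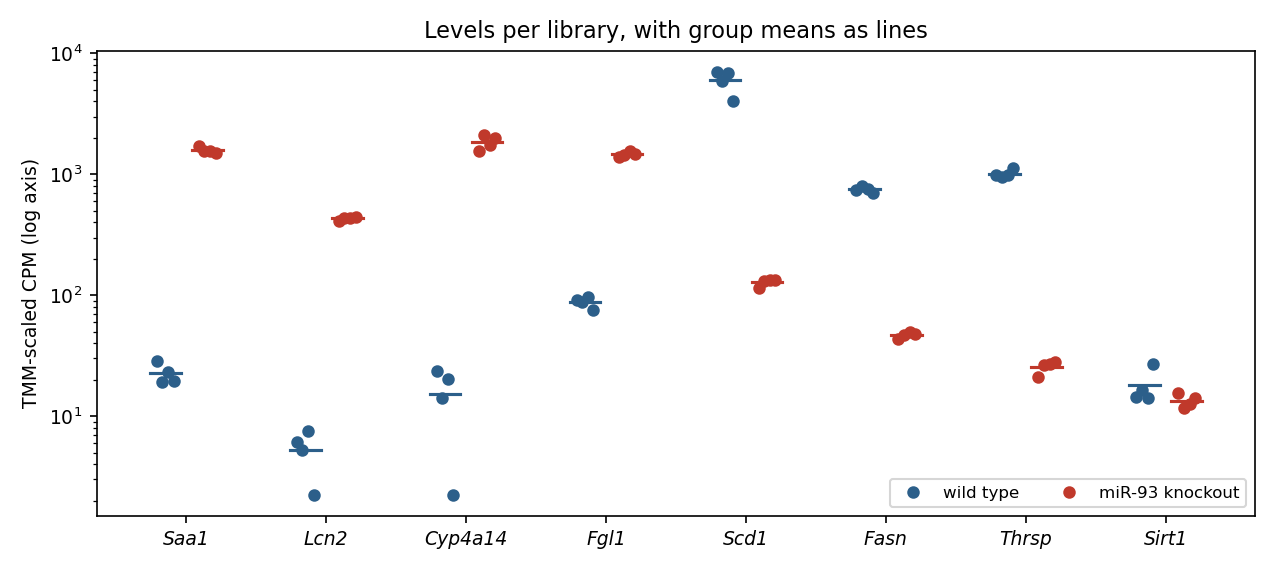
TMM-scaled CPM on a log axis for 8 genes, one point per library (wild type blue, miR-93 knockout red, n = 4 each) with lines at the group means. Saa1, Lcn2, Cyp4a14 and Fgl1 lie higher and Scd1, Fasn and Thrsp lower in all 4 knockout libraries, while the Sirt1 values overlap.

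Of 13204 genes tested, 2777 passed the threshold in edgeR's quasi-likelihood test, 1369 higher and 1408 lower in knockout, and 506 of the higher and 623 of the lower genes changed by at least 2-fold. For 3997 genes (30.3%) the groups did not overlap, a share that chance puts at 2.86%. Without wild-type replicate 4 the count was 4853 of 13777, and all 1369 higher genes and 1404 of the 1408 lower genes stayed called. Leaving out knockout replicate 2, 3 or 4 gave 1494, 1722 and 1489 genes, and leaving out wild-type replicate 2 gave 1796. Scaling by library size alone called 561 genes higher and 124 lower. Of the genes called and named in this Results section, it ended the calls of Nmnat1, Foxo1, Ppargc1b, Insig1, Ulk1, Msmo1, Cyp2c70, Abcb11, Abcb4, Pygl, Col1a2, Cxcl9, Irf7, Ifit3, Psmb9, H2-Q4, Nfe2l2, Sdhd, Atp5b, Per3, Dbp, Per2, Ces2a, Nudt7, Cyp2a4, Cyp17a1, Sds, Rplp0, Trac, Cd4, Trbc2, Cd79a, Atf3, Atf4, Ern1, Xbp1, Alas2 and Hlf. Among genes named only in the closing sections, it ended those of Gls2, Tat, Cish, Igf1, Onecut1, Rdh11, Rbp4 and H2-K1. For genes of this Results section, the replicate block ended the calls of Nmnat1, Foxo1, Ppargc1b, Cyp2a4, Trac, Cd4, Trbc2, Atf3, Atf4 and Hlf, a test without a filter on low counts those of mt-Ts1, Nmnat1, mt-Co1, mt-Co2, Cyp2a4, Trac, Cd4, Trbc2 and Atf4, and thinning to equal nuclear depth those of Nmnat1, Foxo1, Psmb9, Vsig4 and Ern1.

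Genes of fatty acid oxidation rose and genes of fat and sterol synthesis fell. Among 35 tested genes of fatty acid oxidation and PPAR-alpha targets, the genes of the nuclear receptor that drives lipid burning, 31 rose and none fell. Cyp4a14, Cyp4a10, Cyp4a31 and the acyl-CoA thioesterase gene Acot1 (3.68 ± 0.28) had the smallest p-values. In the opposite direction, 19 of 26 genes of fatty acid and triglyceride synthesis fell and none rose, including Thrsp, Fasn, Scd1 and the citrate lyase gene Acly (-3.03 ± 0.15, adjusted p = 3.11e-07). Of 25 genes of cholesterol synthesis and uptake, 19 fell and none rose, among them the sterol synthesis enzyme genes Msmo1 (-1.83 ± 0.13) and Dhcr7 (-2.05 ± 0.16). The list medians were 1.19, -1.06 and -1.51, and adjusted over the list alone 33 rose, 22 fell and 19 fell. Camera placed the 3 lists apart from other genes with the preset correlation (adjusted p = 5.47e-18, 2.19e-17 and 9.18e-12). With an estimated correlation the adjusted p were 0.128, 0.0551 and 0.0643, past the threshold for none of them. Without wild-type replicate 4, 33 genes rose and 22 and 20 fell.

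Lipid droplet and lipid uptake genes also rose, in 13 of 26 tested members with none lower. They included Hsd17b11 (1.68 ± 0.16), the perilipin gene Plin4 (1.58 ± 0.17), the fatty acid translocase gene Cd36 (1.04 ± 0.12) and Mgll (0.98 ± 0.14). Adjusted over the list alone, 15 rose and 2 fell, and the camera adjusted p was 0.000289, or 0.128 with an estimated correlation. Leaving out wild-type replicate 4 gave 15 higher and 3 lower.

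Acute phase genes rose together. Of 25 tested members 24 rose, with a median of 2.11, and the same number passed adjusted over the list alone. Saa1, Saa2, Mt2 and Lcn2 had the smallest p-values. The exception was Hamp, the iron hormone hepcidin, named after its values were seen, at -0.31 ± 0.18 (adjusted p = 0.246), which without wild-type replicate 4 fell (-0.44, adjusted p = 0.000676) and which under library size scaling read 0.17. This list alone stayed called with an estimated correlation (camera adjusted p = 0.0165, against 3.22e-24 with the preset one). Within 15 tested inflammatory cytokine and chemokine genes, Cxcl1 (2.89 ± 0.19, adjusted p = 3.00e-06) and the cytokine-feedback gene Socs3 (1.60 ± 0.19) rose and Cxcl9 fell (-1.78 ± 0.25), and the list was not called (adjusted p = 0.888). The count was the same adjusted over the list alone, and without wild-type replicate 4, 6 of these genes rose and 3 fell.

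**Figure D3:**
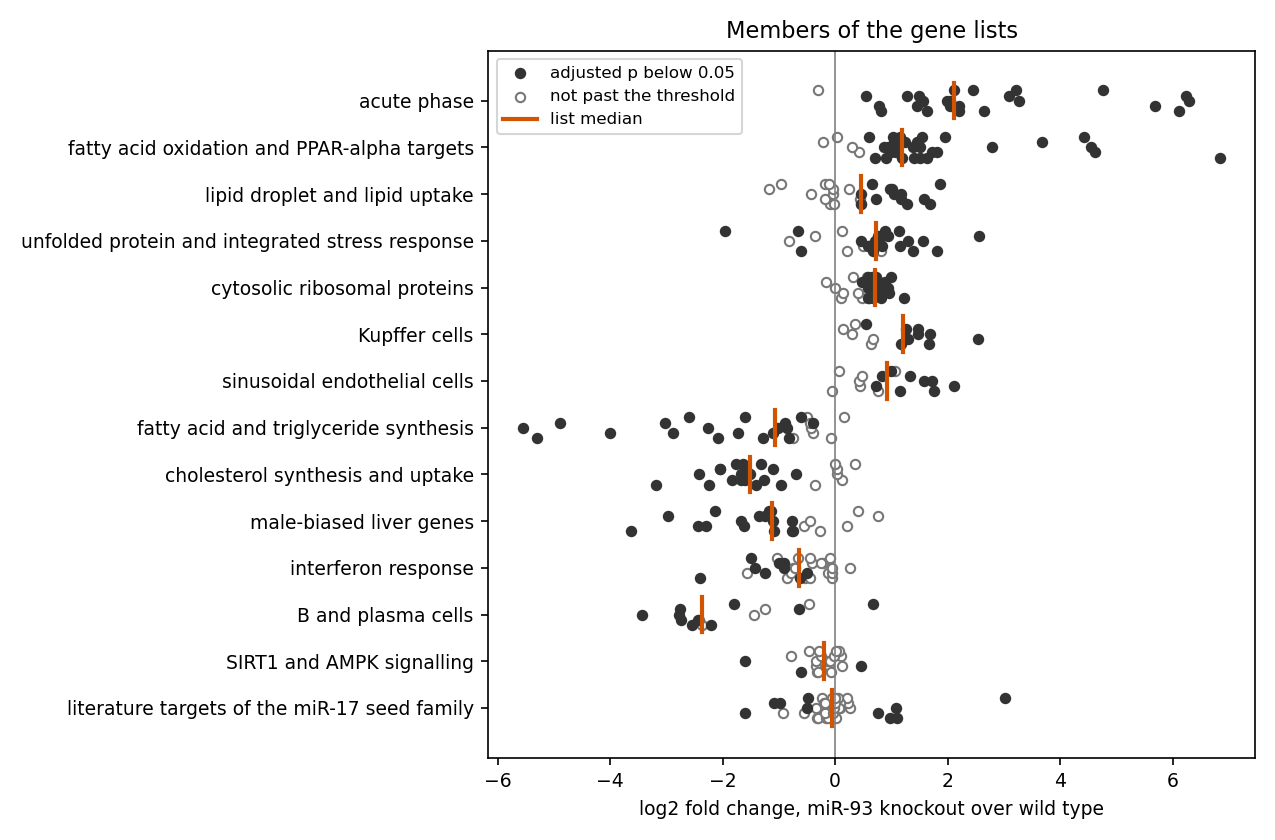
Log2 fold change, knockout over wild type, of every tested member of 14 gene lists, one point per gene. Filled points are past an adjusted p of 0.05 and orange bars are list medians, which run from 2.11 for acute phase genes to -2.37 for B and plasma cell markers.

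Secretory pathway stress genes rose in part. Of 26 genes of the unfolded protein and integrated stress responses, 17 rose, among them the chaperone gene Hyou1 (1.38 ± 0.13), Manf (1.15 ± 0.12), Atf5 (1.29 ± 0.16) and the glutathione-degrading enzyme gene Chac1 (2.56 ± 0.36). Atf4, Ern1 and Atf3, named after their values were seen, fell, at -0.60 ± 0.17, -0.67 ± 0.13 and -1.96 ± 0.53. The calls of Atf3 were lost without knockout replicate 2, 3 or 4 or wild-type replicate 2 (adjusted p 0.0592 to 0.0881) and those of Atf4 without any of the 4 knockout libraries in turn (0.0640 to 0.0916), and Atf4 read 0.07 under library size scaling. Ern1 was not called after thinning to equal nuclear depth (0.103) or with library size only (-0.10, 0.863). Adjusted over the list alone 18 rose and 3 fell, and the list had a camera adjusted p of 5.11e-05, or 0.118 with an estimated correlation. Of 33 cytosolic ribosomal protein genes 24 rose (27 adjusted over the list alone), with Rpl4 at 1.22 ± 0.17 and Rplp0 at 0.96 ± 0.15 (list median 0.70, camera adjusted p = 3.42e-10, 0.321 with an estimated correlation).

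Sex-biased liver genes, which in male mice follow pulsatile growth hormone, shifted in both directions. Of 22 male-biased genes 16 fell and none rose, led by Selenbp2 (-3.63 ± 0.21), the elongase gene Elovl3 (-2.44 ± 0.16), Nudt7 (-1.67 ± 0.13) and the steroid dehydrogenase gene Hsd3b5 (-2.97 ± 0.24), with 18 lower and 2 higher adjusted over the list alone. Of 25 listed female-biased genes only 12 passed the filter on low counts, which can keep a gene that is high in a single genotype. The counts therefore describe the tested members only. Of these 12 genes 6 rose and 2 fell (8 and 2 adjusted over the list alone): Fmo2 was at 1.56 ± 0.17 and Acot3 at 1.48 ± 0.17, against Cyp2a4 at -1.87 ± 0.42 (not called without a filter on low counts, with the replicate block or with library size only) and Cyp17a1 at -0.74 ± 0.17 (-0.09 and not called with library size only). The camera adjusted p were 4.24e-09 and 0.00509, or 0.118 and 0.128 with an estimated correlation, and without wild-type replicate 4 the female-biased count was 10 higher and 2 lower. After thinning to equal nuclear depth the female-biased list was not called (adjusted p = 0.129). Its median was 0.29 over the members that the filter still kept, against 1.06 over the 12 tested before, so both may cover different genes. The Y-linked gene Ddx3y had 71 to 608 counts in every library and Xist 0 to 3, so no library carried a female pattern. Circadian clock genes fell in 7 of 18 cases, including Per3 (-1.06 ± 0.13), Dbp (-0.94 ± 0.12) and Per2 (-0.83 ± 0.16), while Nfil3 (2.11 ± 0.34) and Hlf (0.89 ± 0.25, named after its values were seen) rose, with 10 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.0107, 0.142 with an estimated correlation). Under library size scaling the clock median turned from -0.37 to 0.13, below the shift of all genes, and the list was not called (camera adjusted p = 0.147). Without wild-type replicate 4, 12 clock genes fell. Hlf was not called without knockout replicate 2, 3 or 4 or wild-type replicate 2 (adjusted p 0.0729 to 0.0915).

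Interferon response genes fell in 9 of 28 cases with none higher, among them Ifit1 (-2.40 ± 0.30), Irf7 (-1.24 ± 0.17), Ifit3 (-1.42 ± 0.21) and the immunoproteasome gene Psmb9 (-0.91 ± 0.16, not called after thinning to equal nuclear depth). Adjusted over the list alone 11 fell (median -0.64, camera adjusted p = 3.99e-05, 0.0551 with an estimated correlation), and 15 fell without wild-type replicate 4. Antigen presentation genes fell in 3 of 15 cases, led by H2-Q4 (-0.86 ± 0.16). That list (camera adjusted p = 0.0431, 0.321 with an estimated correlation) was no longer called with library size only (0.0545) or without knockout replicate 1 or 3 or wild-type replicate 1 or 3 (adjusted p 0.0566 to 0.160), and 3 of its genes fell adjusted over the list alone, against 7 over all genes without wild-type replicate 4.

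Markers of the non-parenchymal liver cells moved apart. Of 14 Kupffer cell markers, genes of the resident liver macrophages, 9 rose and none fell, with C1qc at 1.66 ± 0.26, the scavenger receptors Cd163 at 2.53 ± 0.40 and Marco at 1.47 ± 0.29, and the complement receptor Vsig4 at 1.25 ± 0.28 (not called after thinning to equal nuclear depth, adjusted p = 0.0665). Of 16 sinusoidal endothelial markers 9 rose and none fell, including Lyve1 (2.11 ± 0.32), Oit3 (1.76 ± 0.27), Gpr182 (1.72 ± 0.27) and Kdr (1.33 ± 0.27). In contrast, 9 of 15 B and plasma cell markers fell, with Ighd at -2.55 ± 0.26, the lineage factor Pax5 at -3.43 ± 0.47 and Cd79a at -2.75 ± 0.49, and the 1 that rose, Xbp1 (0.67 ± 0.14), is also a stress response gene and was named after its values were seen. With p-values adjusted over the list alone, 10 Kupffer and 10 endothelial markers rose and 10 B cell markers fell. Of 8 T and NK cell markers Trac (-1.29 ± 0.40), Cd4 (-1.47 ± 0.46) and Trbc2 (-1.13 ± 0.36) fell, with 4 lower adjusted over the list alone. These 3 calls were lost when any single library other than wild-type replicate 4 was left out, apart from Cd4 without knockout replicate 4 (adjusted p 0.0568 to 0.130). The 4 lists had camera adjusted p of 0.000190, 8.71e-05, 0.000289 and 0.0124 in this order. With an estimated correlation the adjusted p were 0.321 for the Kupffer, endothelial and B cell lists and 0.128 for T and NK cells. After thinning to equal nuclear depth the B cell list was not called (adjusted p = 0.433). Its median was -1.06 over the members that the filter still kept, against -2.37 over the 15 tested before. Both medians may cover different genes, so this is no measure of a smaller change. The mean Kupffer marker level of wild-type replicate 4, 3.78 on the log2 CPM scale, lay within the knockout range of 3.51 to 3.86, and without this library 13 of the 14 Kupffer markers and 14 of the 16 endothelial markers rose. Hepatocyte markers went both ways, 5 higher and 2 lower of 15 (adjusted over the list alone 5 and 3, without wild-type replicate 4 5 and 4). Camera did not call the hepatocyte list (adjusted p = 0.304), while the alternative test, fry, did (adjusted p = 0.0399).

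All 12 tested protein-coding genes of the mitochondrial genome fell, by log2 values from -2.73 to -3.46 (median -3.14, all 12 adjusted over the list alone). The cytochrome oxidase genes mt-Co1 and mt-Co2 stood at -3.40 ± 0.74 and -3.46 ± 0.76, and mt-Nd4l at -2.74 ± 0.57. Without wild-type replicate 4 all 12 still fell and the median was -1.78, while with the replicate block 8 fell and without a filter on low counts mt-Co1 and mt-Co2 were not called (adjusted p 0.0725 and 0.0753). The camera adjusted p was 3.60e-06, or 0.321 with an estimated correlation. Of 38 oxidative phosphorylation genes encoded in the nucleus, 8 rose and 1 fell, in the whole set and adjusted over the list alone, with Sdhd at 0.93 ± 0.19 and Atp5b at 0.81 ± 0.18. That call (camera adjusted p = 0.0329, 0.782 with an estimated correlation) was lost without wild-type replicate 4 (adjusted p = 0.782), where 10 rose and 8 fell, and also with library size only (0.271) and with fry (0.369). Sdhd and Atp5b were not called with library size only (0.0724 and 0.112).

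The zones of the liver lobule and the drug-metabolising genes differed less clearly. Of 19 genes of hepatocytes around the central vein 8 rose and none fell, with glutamine synthetase, Glul, at 1.69 ± 0.14 and Cyp2e1 at 2.39 ± 0.22, and of 21 genes of hepatocytes around the portal tract 9 fell and 2 rose, with the serine dehydratase gene Sds at -1.67 ± 0.14 and Ctsc at 1.79 ± 0.17 (list median -0.37, or 0.16 under library size scaling). Of 22 xenobiotic metabolism genes 8 rose and 1 fell, Cyp3a13 at 2.20 ± 0.16 and Ces2a at -1.60 ± 0.15, and of 28 autophagy and lysosome genes 10 rose and 1 fell, Gabarapl1 at 1.13 ± 0.15 and Ulk1 at -0.99 ± 0.12. Adjusted over the list alone the counts were 8 higher and 1 lower, 10 lower and 2 higher, 10 higher and 2 lower, and 11 higher and 2 lower. The camera adjusted p of the 4 lists were 0.0212, 0.0398, 0.0431 and 0.0312, and with an estimated correlation the adjusted p were 0.321, 0.369, 0.321 and 0.330. The pericentral call was lost without wild-type replicate 4 (0.184), the periportal one without knockout replicate 1 or wild-type replicate 1 or 3 (0.0720 to 0.141), and the xenobiotic one without any single library other than wild-type replicate 2 (0.0546 to 0.196). The xenobiotic call was also lost with the replicate block (0.0580). With library size only none of the 4 was called (0.0616 to 0.148). Without wild-type replicate 4, 3 pericentral genes fell, and the counts were 11 higher and 4 lower for the xenobiotic and 13 and 4 for the autophagy list.

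Several lists with changed members were not called as sets by camera, whose adjusted p are given here. Of the gene lists among them, fry called cell cycle (adjusted p = 0.0285) and immediate early and heat shock genes (0.0399). Fibrosis and extracellular matrix genes fell in 6 of 24 cases, with Col3a1 at -1.85 ± 0.19 and Col1a2 at -1.30 ± 0.26, and Fn1 rose (0.83 ± 0.19; list adjusted p = 0.175). Bile acid genes split into 6 higher and 7 lower of 29, with Cyp2c70 at -1.65 ± 0.15 and the bile salt export pump gene Abcb11 at -0.90 ± 0.12 against Abcb4 at 0.81 ± 0.12 (0.888). Gluconeogenesis and insulin response genes split into 4 and 4 of 19, with the glucose-6-phosphatase gene G6pc at -2.17 ± 0.14 and Pygl at -1.28 ± 0.12 against Igfbp1 at 1.84 ± 0.21 and Pdk4 at 1.96 ± 0.35 (0.616). NRF2 and glutathione genes fell in 11 of 31 cases and rose in 2, with Gsta1, Gstm3 and the regulator gene Nfe2l2 (-1.28 ± 0.14) among the lower ones (0.291). Cell cycle genes fell in 4 of 18 cases, including E2f2 (-2.97 ± 0.46), while the inhibitor gene Cdkn1a rose (3.01 ± 0.38; 0.0547). Immediate early and heat shock genes rose in 7 and fell in 4 of 21 cases (0.162). Adjusted over the list alone, the higher and lower counts of these lists were 2 and 6, 8 and 8, 7 and 5, 2 and 11, 1 and 7, and 8 and 5. Without wild-type replicate 4 the NRF2 and cell cycle lists passed as lower (0.0261 and 0.00161), as they did with library size only (0.0217 and 0.000431) and the cell cycle list with the replicate block (0.0358), and the counts of the bile acid list were 9 higher and 9 lower, of the gluconeogenesis list 7 and 6, of the fibrosis list 4 and 6, of the NRF2 list 5 and 13 and of the cell cycle list 1 and 7. The median and mean of the bile acid, gluconeogenesis, NRF2 and adipocyte lists differed in sign. Of the other marker lists, stellate cells and fibroblasts had 0 of 16 genes past the threshold, lipid-associated macrophages 1 higher and 2 lower of 11, cholangiocytes 1 higher of 5, erythroid cells 2 lower of 7 with Alas2 at -1.49 ± 0.12, and adipocytes 1 higher and 1 lower of 6, the lower one being the muscle and fat carbonic anhydrase gene Car3 (-3.59 ± 0.40). Alas2 and Car3 were named after their values were seen. Adjusted over the list alone the counts were 0, 1 higher and 2 lower, 1 higher, 3 lower, and 2 higher and 1 lower. None of these was called by camera (adjusted p from 0.304 to 0.888), although cholangiocytes passed as higher without wild-type replicate 4 (0.0434). The alternative set test, fry, called cholangiocytes (adjusted p = 0.00641) and erythroid cells (0.0399). Without that library 3 stellate cell genes rose and 1 fell, 2 macrophage genes rose, and 2 adipocyte genes rose and 2 fell. Monocytes and dendritic cells, neutrophils, pancreatic acinar cells, and mesothelium and gallbladder had 4, 2, 2 and 1 tested markers, too few for the set test, and none of these passed singly, although without wild-type replicate 4 1 monocyte and dendritic cell marker rose and 1 acinar marker fell.

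The question of direct miR-93 targets was put to the 3′ UTRs. Published targets of the miR-17 seed family, to which miR-93 belongs, went both ways: of 35 tested, 5 rose and 5 fell, in the whole set and adjusted over the list alone. Stat3 (1.09 ± 0.12) and Ppara (1.08 ± 0.13) were among the higher genes and Insig1 (-1.61 ± 0.19) and the autophagy kinase gene Ulk1 among the lower ones (camera adjusted p = 0.684). Of 11572 tested genes with an annotated 3′ UTR, 1689 held GCACTTT, the match to miR-93-5p positions 2 to 8. With UTR length as a covariate their mean log2 fold change lay 0.04 above that of the other 9883. Set among all 419 other 7-mers with the same bases, the seed held rank 84 by the size of this difference (two-sided p = 0.20 by exact enumeration). The middle 95% of the other 7-mers spanned -0.06 to 0.07, and camera with the preset correlation gave an unadjusted p of 0.584. Many of the 7-mers ranked above the seed hold CG, among them CTATTCG (0.117), TACGCTT (0.107) and TCATTCG (-0.0901). The rank therefore depends on which 7-mers are the controls. Another of them, CACTTTG (0.0609), is itself a match to the first bases of miR-93-5p. A ranking against 7-mers without CG was not made. Beyond the 7-mers used, a rise of genes with seed sites was not detectable.

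**Figure D4:**
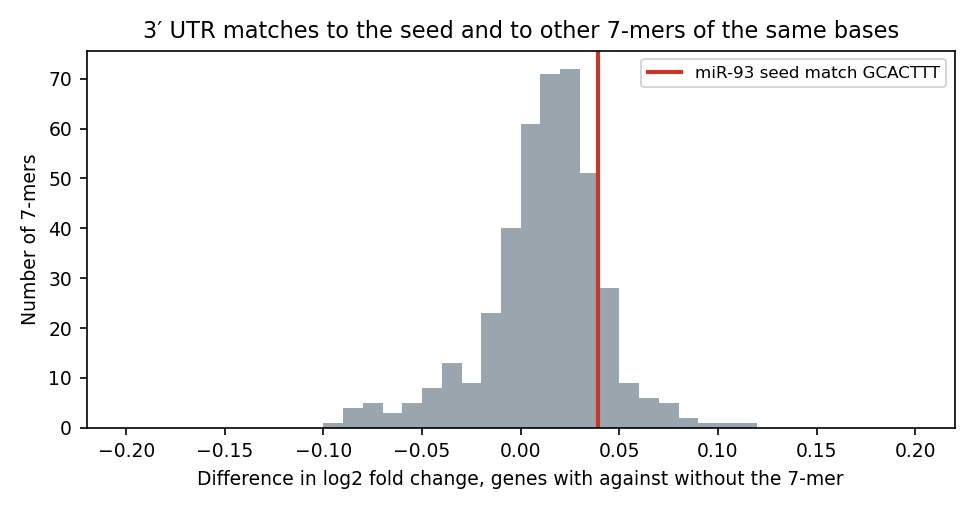
Difference in log2 fold change between genes with and without a 7-mer in the 3′ UTR, adjusted for UTR length, as a histogram over 419 other 7-mers of the same base composition, with the miR-93 seed match as the red line at 0.04. The seed lies inside the spread of the other 7-mers, with rank 84 by size.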

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

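The tests of wild-type replicate 4 alone, of fasting, of a wrong label, of the hepatocyte share and of the B cell markers other than immunoglobulin genes were chosen only after the result was seen. In 10 of 104 checks of 4 libraries of 1 genotype, a library lay farther from the other 3 than Dixon's limit allows, where chance gives about 5.2. Of these, 8 concerned wild-type replicate 4 and 2 a knockout library.

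Wild-type replicate 4 had 14287 genes with a count, against 18412 to 19131 in the other wild-type libraries. In log2 CPM it held Cyp4a10 at 3.78 (other wild-type libraries 5.56 to 5.65), Nlrp12 at -2.22 from 0 counts (1.35 to 1.91), Gsta1 at 2.55 (5.15 to 5.36) and Hamp2 at 5.59 (7.26 to 7.39). The mean log2 CPM of its fatty acid and triglyceride synthesis genes was 7.73 (others at most 8.04), of its Kupffer cell markers 3.78 (2.19 to 2.35) and of its sinusoidal endothelial markers 3.51 (3.20 to 3.21). Knockout replicate 1 held Scd1 at 6.84, below the other knockout libraries at 7.03 to 7.07. Knockout replicate 2 had a mean of 5.01 over the antigen presentation genes, against 4.95 in each of the others.

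The first pattern weighed is that wild-type replicate 4 stands apart. Low depth as the whole cause is argued against, because the other 7 libraries, thinned to its number of nuclear counts, detected at least 8.08% more genes than it did. A knockout sample under a wild-type label is argued against as well: over 4754 genes called without this library, it lay on the wild-type side at 73.3%, while knockout libraries left out and placed in the same way did so at 0.749% to 8.16% and wild-type libraries at 70.7% to 90.8%. The bound first set for that share was narrowly missed, and the comparison with left-out knockout libraries was set afterwards. What stays open is the quality of the RNA or the tissue sampled, which no value here decides.

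The second pattern is that acute phase and PPAR-alpha target genes were higher and lipogenic and sterol genes lower in knockout. Wild-type replicate 4 alone is argued against, since 100% of the 93 called members of these 4 lists were called in the same direction without it. The pattern stayed at equal nuclear depth, where no list median moved by more than 0.0813. Thinning leaves the expected fold change of a gene unchanged, so a large move was unlikely and the depth difference is not decided by this. Leaving out the mitochondrial genes moved no list median by more than 0.00765 and the median of all genes by 0.00814. The 4 list medians were then 2.11, 1.18, -1.07 and -1.52, in the order named above. Since the pattern stayed with these reads removed, their entering the scaling is argued against as its cause. This covers the scaling only, not what lies behind the difference in mitochondrial share. Fasting at collection as the whole cause cannot be told apart, since of 9 genes that fasting induces 4 were lower in knockout (G6pc, Sds, Gls2 and Tat, the last 3 not called with library size only and Tat also not with the replicate block or without a filter), 3 were higher (Igfbp1, Pdk4 and Fgf21), and Pck1 (-0.37, called lower with DESeq2, with limma-voom, after thinning and without wild-type replicate 4) and Ppargc1a (-0.08) were not called. An effect of the genotype stays open as a hypothesis, beside differences in feeding, handling or tissue condition that the labels do not give.

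The third pattern is that Kupffer and sinusoidal endothelial markers were higher and B and T cell markers lower in knockout. A smaller share of hepatocytes in the knockout samples, acting alone, would raise every other cell type. It is argued against as the only cause of all 4 lists, as the list medians were 1.21 and 0.91 for Kupffer and endothelial cells but -2.37 and -1.14 for B and T cells. Together with a separate difference in lymphoid cells it could still play a part in the Kupffer and endothelial rise, which these medians do not decide. Lymphoid-rich tissue in single wild-type libraries cannot be told apart for the B cell list as a whole, since 3 of the 4 wild-type libraries, but not replicate 4 (2.26), lay above every knockout library (1.02 to 2.68) in mean log2 CPM. At 6 of the 8 B cell markers other than immunoglobulin genes every wild-type library lay above every knockout library, where chance gives 0.114 markers. Groups did not overlap, in either direction, at 30.3% of all tested genes, so chance is too low a baseline. These markers belong to the same cell type and can vary together. At those 6 the difference was not confined to single wild-type libraries, but this does not decide the question for the list. After thinning to equal nuclear depth the call of the B cell list was lost (adjusted p = 0.433), with a median of -1.06 over the members that the filter still kept.

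For the count of genes between the genotypes, 35 splits of the 8 libraries into 4 and 4 were compared. Only 1, the real one, called as many genes, with 2777 against at most 0 in the others. That is the smallest share that 35 splits can give. Every other split mixes the genotypes, which widens the spread within its groups, so 0 calls there add little beyond this rank. Chance is made less likely but is not excluded, and the labels do not say whether the libraries came from separate animals.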

How the results depend on the processing

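The thinned alternative and the one without mitochondrially encoded genes were chosen after seeing the data. The count of genes was 685 (561 higher, 124 lower) with library size only, 4950 (2409, 2541) with quality weights, 667 (317, 350) with a minimum fold of 1.5 and 1590 (781, 809) thinned to equal nuclear depth. Leaving out 1 library gave 1489 to 4853 genes, 760 to 2446 higher and 728 to 2407 lower. With the replicate block it was 1267 (643, 624), but same-numbered libraries correlated at -0.19, -0.03, -0.07 and -0.09, so the numbers do not pair them. A minimum fold asks for a larger change and thinning removes counts; the cause was not tested for the others. Other scalings, filters and tools gave 2542 to 3479 genes, and every gene shared with the reported calls had the same sign in all 20 alternatives. Of 22 lists, 1 stayed called with an estimated correlation. With library size only, which raises the median gene by 0.55, values turned positive but stayed below that shift for Mcm7 (0.30), Sirt1 (0.30), Atf4 (0.066), Hamp (0.17), H2-K1 (0.0077), H2-Q7 (0.075), Pck1 (0.16), Ppargc1a (0.45), the clock list (0.13) and the periportal list (0.16). Leaving out 1 library gave -0.16 to 0.0090 for Ppargc1a, positive without knockout replicate 3. Of 2969 values of 150 called genes under alternatives, 2764 kept direction and call, 203 lost the call and 2 reversed. For the called lists 280 of 328 did, 46 lost the call and 2 reversed. The seed difference stayed past no threshold under its alternatives.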

Other observations

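The gene groups in this part, the 2 near the deleted locus included, were chosen only after seeing the data, apart from the tests of the deleted locus and of glucocorticoid-induced genes, whose bounds were set before their values were seen. Amino acid and urea catabolism genes fell in 12 of 31 cases and rose in 2 (19 and 3 without wild-type replicate 4), with the tryptophan pathway gene Acmsd at -2.65 and the aminotransferase gene Got1 at -2.10 (camera adjusted p = 0.000794, adjusted p = 0.268 with an estimated correlation). With library size only the median of that list turned from -0.43 to 0.06, below the shift of all genes. Of 13 genes of the growth hormone and STAT5 axis, 5 fell and none rose, among them Cish (-2.03), Igf1 (-0.70) and Onecut1 (-1.74) (camera adjusted p = 0.0215, adjusted p = 0.153 with an estimated correlation). The median of that list was -0.28, and with library size only it was 0.26 and the call was lost (adjusted p = 0.0853), as were the calls of Cish (0.0543), Igf1 (0.791) and Onecut1 (0.143). Of the 9 genes that fasting induces, Igfbp1, Pdk4 and Fgf21, the 3 that rose, were left out of a last list. Of its 6 gluconeogenic and amino acid genes 4 fell and none rose, or 5 fell without wild-type replicate 4 (median -0.92, camera adjusted p = 0.000101, adjusted p = 0.107 with an estimated correlation). Leaving out the risen genes set this direction in advance, so these p-values are no evidence for a fall.

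Retinoid handling genes split, 4 higher and 4 lower of 18, with Retsat at 3.45 and Rbp4 at 1.13 against Cyp26a1 at -3.02 and Rdh11 at -1.57 (camera adjusted p = 0.668). With library size only the edgeR calls of Rbp4 (adjusted p = 0.0513) and Rdh11 (0.117) were lost. Complement and coagulation genes rose in 12 and fell in 6 of 31 cases (camera adjusted p = 0.0720, and 0.0115 without wild-type replicate 4), and iron and haem genes rose in 6 and fell in 3 of 21 cases (camera adjusted p = 0.369), or 11 and 6 without wild-type replicate 4.

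A hypothesis is that passenger alleles around the deleted locus may account for calls. Among the 10 nearest tested neighbours Cops6 (1.21) and Zkscan1 (0.94) rose, but 37 of 205 genes within 10 Mb of Mir93 by the GRCm38 annotation were called, a share 0.856 times that elsewhere (Fisher's exact p = 0.342), which argues against such an excess. A second hypothesis is a raised glucocorticoid response, prompted by Fkbp5 (2.25) and Zbtb16 (2.06), which were higher in knockout. Over 8 other glucocorticoid-induced genes the median was 0.28 and 1, Cebpd (0.87), rose (camera adjusted p = 0.238). Without wild-type replicate 4, 4 of the 8 rose with a median of 0.21, while the call of Cebpd was lost without any of the knockout libraries in turn, without wild-type replicate 2 or 3 (adjusted p 0.0618 to 0.0924) and after thinning (0.46, adjusted p = 0.326), so the hypothesis stays open.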
